A study of Mus musculus with 89 samples.

How the data were processed

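Single cells were sorted from the dissected dentate gyrus of mice that carry a nuclear fluorescent reporter under the Nestin promoter, and each cell was amplified and sequenced on its own with a full-length, template-switching kit. Each of the 89 deposited samples is 1 cell, 48 of them from mice of 2 months and 41 from mice of 4.5 months. No label names the animal a cell came from. What the numbers in the sample titles stand for is not stated, and they were read as cell names only. Each age was therefore treated as 1 sample, so that no test between the ages was run and no p-value, standard error or count of changed genes is given.

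The authors deposited a table of estimated counts per gene and cell, and the deposited second table holds TPM (length-scaled transcript abundance), which sum to 1000000 in every cell. A further deposited table gives each cell a class (qNSC, aNSC or IPC, read here as quiescent neural stem cell, activated neural stem cell and intermediate progenitor cell) and a colour code. How the classes were assigned and what the colours stand for is not stated. The submitters' processing notes name STAR, RSEM and the mouse genome build mm10. Both tables list 24411 genes, of which 16234 had a read in at least 1 cell. No gene name in them starts with the prefix of mitochondrially encoded genes, so the share of mitochondrial reads could not be computed. Of the count values above 0, 4.44% were not whole (tolerance 1e-06), and they were rounded to whole numbers where intervals and detection needed counts.

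Counts were scaled to CPM, counts per 1000000 counts, in each cell and taken as log2(CPM + 1). For each gene and group, 3 quantities were computed: the mean log2(CPM + 1) with its SD over cells, the share of cells with a read with its exact Clopper-Pearson 95% interval, and the CPM of the counts summed over the group's cells with an exact Poisson 95% interval. Where a gene had no read in a group, its fold difference was bounded with a floor of 3 counts over the group. The SD describes the spread between cells, not between animals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

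The age groups were compared over all cells, over the qNSC and aNSC cells together and within each class, and the classes were compared with each other (aNSC against qNSC, IPC against aNSC). Since the classes were presumably drawn from the same expression values, differences between them are in part built in. The choices, the gene lists and the rule for the genes named were fixed before the data were examined, except where stated. In each comparison the rule took genes with a read in at least 20% of the cells of either group, a difference of at least 1 in mean log2(CPM + 1), a ratio of summed CPM of at least 2 and a difference of at least 15 percentage points in the share of cells, all in 1 direction. The 12 genes with the largest difference each way were kept, leaving out predicted genes, pseudogenes, Xist and Y-linked genes. Added to these were genes fixed beforehand, among them Abl1, Nes, Gfap, Hopx, Eomes, Dcx, Mki67, Ccnd2, Apoe, Aldoc, Id3, Id4, Cdkn1b, Cdkn1a, Huwe1, Frzb and Egfr, and 3 members of each gene list that stood apart. Marker genes of 12 cell types were also fixed beforehand.

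Of 33 gene lists, 32 had at least 3 members read in 10% of the cells of either group; the list of mitochondrially encoded genes had none. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on expression in 20 bins. A list at or below percentile 2.5 or at or above percentile 97.5 is said to stand apart. By chance 1.6 of the 32 lists would do so in each comparison if their members were random genes. This compares a list with other genes of the same cells; genes are not independent replicates, and the percentile says nothing of how animals vary. An activation score per cell was the mean standardised log2(CPM + 1) of 68 cell cycle and progenitor genes minus that of 17 stem cell identity genes. For values sensitive to depth, cells were also thinned to 444835 reads, a depth that 80 cells reached.

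The procedure was tested on simulated data shaped like the qNSC age comparison, with 9375 genes. For 50 genes in each setting, the direction was recovered in 50 at a 16-fold increase, 48 at a 4-fold increase, 48 at a 4-fold decrease and 50 at a 16-fold decrease. All 12 genes named in each direction had been altered. The altered list of 30 genes fell at percentile 100, and 6 of 100 unaltered lists stood apart. Genes were drawn independently here and the unaltered lists were random genes, so about this rate was set in advance. The rate for lists whose genes vary together was not tested.

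Gene positions are those of a GENCODE annotation of mm10 and were found for 280 of the 282 genes named. The library kit does not record the strand, so reads of genes with overlapping exons cannot be assigned with certainty, and the same holds for ribosomal protein genes and their pseudogenes. The alternatives were the deposited TPM, median-of-ratios size factors on 196 genes read in at least 95% of cells, centring on 727 genes read in at least 80% of cells, pseudocounts of 10 and 0.1, summed counts, thinning, gene filters, detection at 10 reads, medians over cells, leaving out the 2 highest cells of each gene in each age, subsets of cells, and other clusterings. Leaving out cells with at least 50% of the markers of another cell type, astrocytes aside, at 10 reads, leaving out X- and Y-linked genes, leaving out qNSC cells led by astrocyte or other markers, and thinning the depth comparison were added after the data had been seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.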

Results

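The series asks how stem cells of the mature dentate gyrus and their immediate progeny differ between mice of 2 and 4.5 months. It holds 48 cells of 2-month mice and 41 cells of 4.5-month mice. Total counts per cell ran from 234607 to 1896072 with a median of 912391, and cells had reads of 2156 to 6046 genes. The median cell had 949981 counts and 4076.5 genes at 2 months, and 884721 counts and 3727 genes at 4.5 months. Thinned to the same number of reads, the medians were 3772.5 and 3609.5 genes, with 6 and 3 shallow cells left out. A run of 2-month cells with neighbouring title numbers all had low totals, from 252274 to 568896 counts. It held qNSC, aNSC and IPC cells, and whether the numbers reflect a batch is not stated. There was 1 sample per age, so the age differences that follow are sizes in these cells and cannot be set against a spread between animals.

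The classes had similar shares at the 2 ages. At 2 months 32 of 48 cells were qNSC (66.7%, 95% interval 51.6 to 79.6), 11 were aNSC (22.9%, 12.03 to 37.3) and 5 were IPC (10.4%, 3.47 to 22.7). At 4.5 months 28 of 41 were qNSC (68.3%, 51.9 to 81.9), 7 were aNSC (17.1%, 7.15 to 32.1) and 6 were IPC (14.6%, 5.57 to 29.2). These intervals overlap, so a difference in class shares was not detectable with these numbers of cells. When cells were clustered anew by k-means, the classes were not recovered: 2 clusters held 30 qNSC cells each, with 3 and 4 aNSC cells, and the other held 11 aNSC and all 11 IPC cells.

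Marker genes set the classes apart and also placed some cells with other types. Hopx, a homeodomain gene of quiescent stem cells, had 10 or more reads in 59 of 60 qNSC, 10 of 18 aNSC and 7 of 11 IPC cells. Eomes, a transcription factor of intermediate progenitors, had 10 or more reads in 7 of 11 IPC cells and in 0 of 60 qNSC and 0 of 18 aNSC cells. The astrocyte markers, many of which stem cells also express, were the leading marker set in 37 of the 60 qNSC cells, 15 of 32 at 2 months and 22 of 28 at 4.5 months, and at least 50% of them had 10 or more reads in 50 of the 60. At least 50% of the oligodendrocyte precursor markers had 10 or more reads in 7 of the 18 aNSC cells, 4 at 2 months and 3 at 4.5 months. Pdgfra, the growth factor receptor of these precursors (chromosome 5, 75152292 to 75198215), had 531 to 3057 reads in these 7 cells and 10 or more reads in 0 of the other 82 cells, which allows a share of up to 4.40%. Sox10, Neu4 and Lhfpl3 gave the same split, with at least 86, 195 and 1043 reads in the 7 cells. Olig1, Olig2 and C1ql1 had at least 2901, 477 and 334 reads there, but also 10 or more reads in 26, 11 and 9 of the other 82. Hopx, Gfap and Sox9 had 10 or more reads in 0 of these 7 cells and in 10, 9 and 11 of the other 11 aNSC cells. Abl1, a tyrosine kinase gene named beforehand (chromosome 2, 31688376 to 31804227), had a read in 5 of these 7 cells, 2 of the other 11 aNSC, 7 of 60 qNSC and 5 of 11 IPC cells. In addition, 3 qNSC cells had at least 50% of the oligodendrocyte markers, 1 qNSC cell at 4.5 months had as many endothelial markers, and 1 aNSC cell at 2 months had endothelial and mural markers. Quiescent stem cell markers reached 50% in 53 qNSC, 10 aNSC and 3 IPC cells, intermediate progenitor markers in 9 IPC cells and neuroblast markers in 2 IPC cells. Microglial, ependymal, red blood cell and mature granule neuron markers reached 50% in 0 cells. The 50% limit was set after the cells had been seen. It gave 12 cells with markers of other types, astrocyte markers not being counted.

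**Figure D1:**
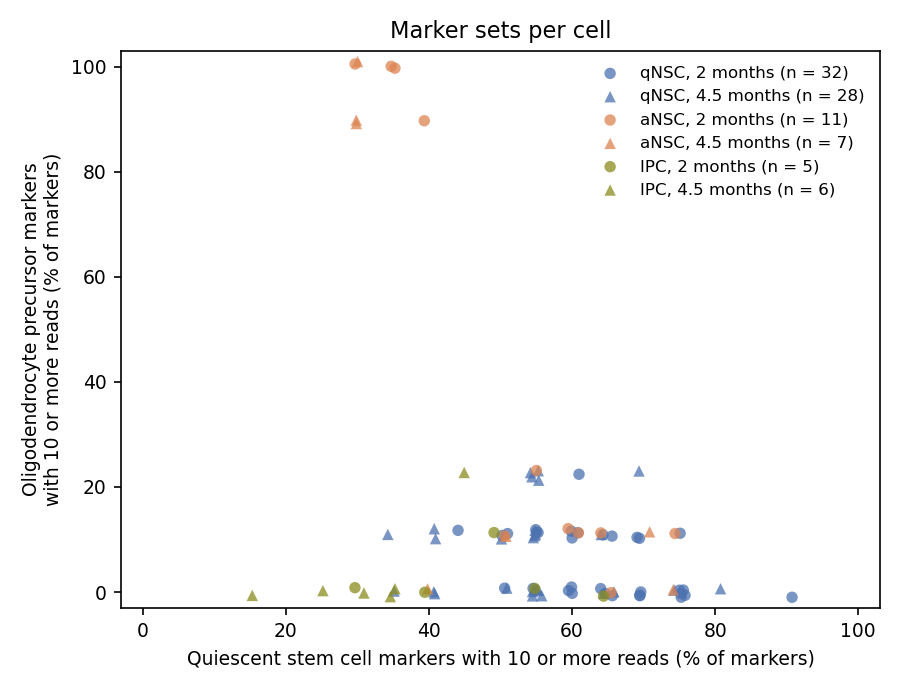
Oligodendrocyte precursor and stem cell markers in the deposited classes, 1 point per cell. Pdgfra has 531 to 3057 reads in 7 aNSC cells and at most 1 read in the other 82 cells, while Hopx, Gfap and Sox9 stay below 10 reads in the same 7 cells.

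The comparison of aNSC with qNSC cells asks what separates activated from quiescent stem cells. Genes of DNA replication and protein synthesis were higher in the 18 aNSC cells than in the 60 qNSC cells. All 24 measured genes of the G1/S list were higher (median difference 1.73 in mean log2(CPM + 1), percentile 100), among them Mcm7, a subunit of the replicative helicase, at 4.80 ± 4.11 against 0.70 ± 2.30 (SD over cells) and in 61.1% against 10.0% of cells. Ribosomal protein genes were higher for 80 of 81 (median 1.84, percentile 100). Cct5, a subunit of a cytosolic chaperonin, stood at 8.78 ± 0.99 against 4.57 ± 3.89, and Cdk4, a kinase that drives cells through G1, at 7.67 ± 2.24 against 3.56 ± 3.64. Proteasome (33 of 37 higher), spliceosome (29 of 30), translation factor (52 of 57), immediate early gene (15 of 16), chaperone (25 of 26), progenitor identity (5 of 6) and G1 cyclin (9 of 10) lists also stood apart, with medians of 1.40, 1.502, 1.18, 1.65, 1.17, 2.19 and 1.39.

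Stem cell and astroglial genes were lower in aNSC cells. Of the 19 measured stem cell identity genes 16 were lower (median -2.03, percentile 0), with Hopx at 5.87 ± 5.18 against 10.60 ± 1.54 and Aldoc, a glycolytic enzyme of astroglia, at 10.28 ± 2.84 against 13.68 ± 0.68. Gjb6 and Gja1, which form astroglial gap junctions, differed by -6.14 and -5.63, and the water channel Aqp4 by -4.40. Msmo1, an enzyme of cholesterol synthesis, differed by -4.43, and 18 of 22 lipid and cholesterol synthesis genes were lower (median -0.55, percentile 0). Growth factor receptors (10 of 16 lower, median -0.65), GABA and glutamate receptors and transporters (11 of 19, -0.34), oxidative stress defence (15 of 26, -0.24) and interferon genes (10 of 16, -0.17, but 0.08 without cells that had markers of other types) stood apart below the random lists. So did fatty acid oxidation, whose median of -0.03 was 0.08 with the deposited TPM, and the quiescence regulators, whose median of 0.08 lay at percentile 1.92. The median over all measured genes was 0.63 higher in aNSC cells, and lists were judged against that.

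The 7 cells with precursor markers bear on this comparison. Without the 12 cells that had markers of other types, 12 rather than 17 lists stood apart and 19 of the 24 genes named by the rule still met it. The stem cell identity list then had a median of -0.66 rather than -2.03 and lipid synthesis -0.19 rather than -0.55, both still apart, and growth factor receptors -0.38 rather than -0.65. The Hopx difference was -1.31 rather than -4.73, Gja1 -2.47 rather than -5.63, Aldoc -2.18 rather than -3.40, Olfm2 0.97 rather than 4.31 and Sulf2 0.64 rather than 4.12, while Id4 and Sox9 changed direction (-2.94 to 0.22 and -2.65 to 0.76). The quiescence regulators moved to percentile 70.6, fatty acid oxidation to 31.1, interferon genes to 8.87, oxidative stress defence to 5.4, G1 cyclins to 82.2 and chaperones to 92.4. Chaperones also lay at 96.5 with the deposited TPM, with a median of 1.17, and G1 cyclins at 94.8 in thinned cells, with 1.45. These medians were about as large as in the main comparison or larger. With a pseudocount of 10, translation factors lay at 96.955 and quiescence regulators at 6.6. In thinned cells the quiescence regulators lay at 3.3. C1ql1, Lhfpl3, Pdgfra, Olig2 and Neu4, all precursor markers, were among the 50 genes that most set aNSC cells apart from the other classes.

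IPC cells were compared with aNSC cells, of which 7 of 18 carried oligodendrocyte precursor markers, so that the aNSC side is not made up of stem cells alone by its markers. Cell cycle genes were higher in the 11 IPC cells without exception among those measured, 42 of 42 in the G1/S list (median 2.36) and 50 of 50 in the G2/M list (median 2.79). Hmgb2, a chromatin protein of dividing cells, stood at 10.41 ± 1.69 against 3.88 ± 4.24, and Ezh2, a histone methyltransferase, at 8.19 ± 1.10 against 1.82 ± 2.93. Ccnd2, a G1 cyclin, stood at 10.29 ± 3.48 against 5.0 ± 3.87. Progenitor and neuroblast identity genes were higher for 14 of 15 (median 3.61), with Igfbpl1 at 5.75 ± 3.15 against 0.17 ± 0.73 and Mfap4 at 8.25 ± 2.94 against 0.98 ± 2.91. Ribosomal proteins, G1 cyclins, spliceosome, p53 and DNA damage, chromatin regulator and translation factor lists stood apart above the random lists, with medians of 1.49, 1.77, 1.37, 1.10, 0.81 and 0.80.

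Metabolic, lysosomal and surface genes were lower in IPC cells. Lysosome and autophagy genes were lower for 28 of 30 (median -1.66), glycolysis genes for 15 of 18 (median -1.57) and fatty acid oxidation genes for 18 of 20 (median -1.53). Clu, a secreted chaperone of astroglia, stood at 2.13 ± 2.31 against 10.76 ± 1.9, and Cspg5, a brain proteoglycan, at 1.10 ± 2.69 against 10.08 ± 1.69. Ttyh1 and Chpt1 had no read in 11 IPC cells and were read in 16 of 18 aNSC cells each, at least about 1508-fold and 1803-fold lower in summed CPM. GABA and glutamate receptors and transporters (16 of 19 lower), growth factor receptors (11 of 12), extracellular matrix (17 of 19), stem cell identity (13 of 17), inflammatory signalling (14 of 15), oxidative stress defence (18 of 27) and Notch signalling (12 of 19) also stood apart. Their medians were -1.75, -1.69, -1.57, -1.47, -1.37, -0.997 and -0.996. Without the cells with markers of other types, 22 lists stood apart. Notch signalling moved to percentile 22.3 with a median of -0.20. Translation factors moved to 87.2, although their median of 0.75 was close to that with all cells.

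**Figure D2:**
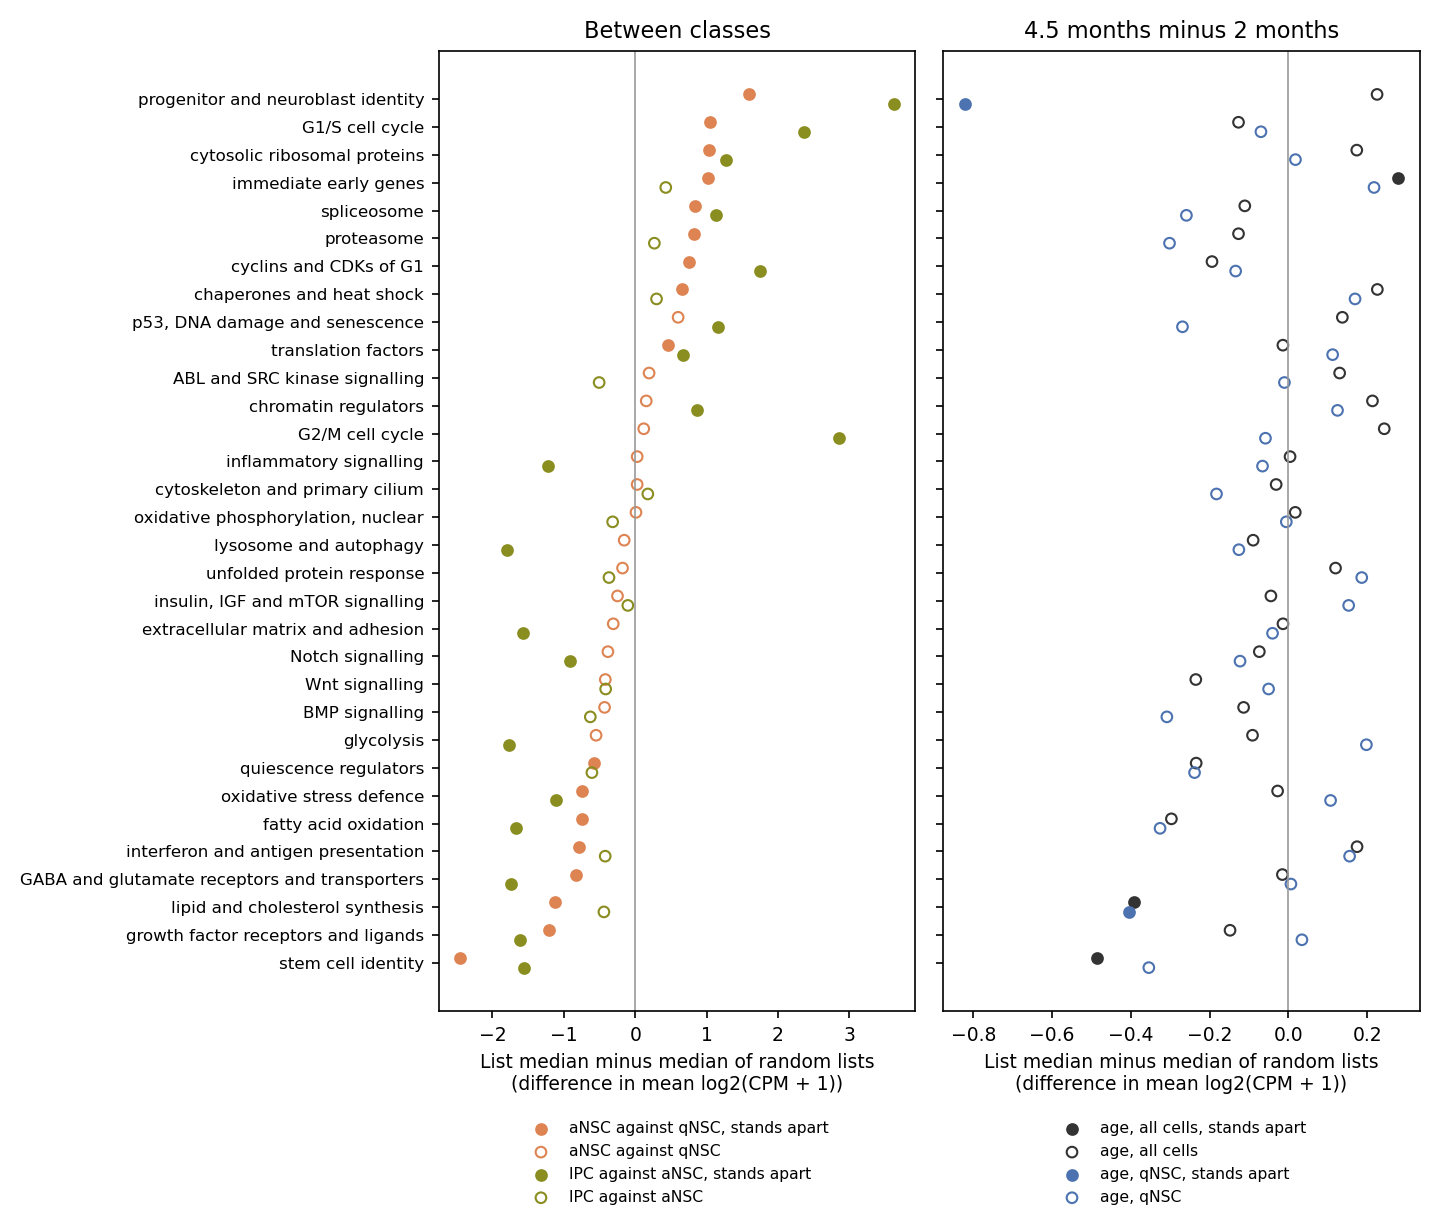
Median difference of each gene list less the median of random lists matched on expression, between classes (left) and between ages (right), in mean log2(CPM + 1), with filled points for lists that stand apart. 17 and 19 of 32 lists stand apart between classes, and 3 (all cells) and 2 (qNSC cells) between ages. Lists of random genes would give 1.6 by chance.

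The central comparison is between the ages. Over all cells, genes of cholesterol synthesis and of stem cell identity were lower at 4.5 months. Sqle, which makes squalene epoxide on the way to cholesterol (chromosome 15, 59315077 to 59331192), stood at 3.80 ± 3.87 in 41 cells against 6.93 ± 3.44 in 48 cells at 2 months and had a read in 56.1% (39.7 to 71.5) against 83.3% (69.8 to 92.5) of cells. Its summed CPM was 142 (139 to 146) against 388 (382 to 394). Idi1 and Hmgcs1, enzymes of the same pathway, differed by -2.88 and -2.06, and 18 of 22 genes of the lipid and cholesterol synthesis list were lower (median -0.66, percentile 0.62). Of 17 stem cell identity genes 15 were lower (median -0.78, percentile 0.27), among them Hes5, a Notch target that keeps stem cells undifferentiated (chromosome 4, 154960923 to 154962371), read in 41.5% against 79.2% of cells. In qNSC cells the astrocyte set led in 22 of 28 cells at 4.5 months and 15 of 32 at 2 months. The median share of astrocyte markers with 10 or more reads was 66.7% and 62.5%, and that of stem cell markers 55% and 65%. These stem cell markers are the genes of the stem cell identity list. Their share, and in part the lead of the astrocyte set, are thus not separate evidence.

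Gfap, the filament protein of radial glia, was read in 61.0% (44.5 to 75.8) of 4.5-month cells and 87.5% (74.8 to 95.3) of 2-month cells, while its summed CPM was nearly equal, 364 and 382. Immediate early genes, which respond to stimulation within minutes and also to tissue dissociation, were the list that stood apart above the random lists (10 of 16 higher, median 0.11, percentile 97.9). Fosb was read in 9 of 41 against 3 of 48 cells and Btg2 differed by 1.06. Among the genes named by the rule, Dab1, an adaptor of Reelin signalling, was lower (2.49 ± 3.29 against 5.47 ± 3.37), as was Rela, a subunit of NF-kappa-B (2.10 ± 3.27 against 4.56 ± 3.50). Higher ones included Clic4 (4.15 ± 3.75 against 2.07 ± 3.24), the matrix protein gene Prelp (5.38 ± 3.91 against 3.47 ± 3.82) and Abcf1 (4.20 ± 3.38 against 2.22 ± 3.02). Abl1 had a read in 9 of 41 and 10 of 48 cells.

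Sex-linked transcripts differed between the ages without overlap at 10 reads. At 2 months 38 of 48 cells had 10 or more reads of a Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) and 0 had 10 or more reads of Xist or Tsix, while at 4.5 months the counts were 0 and 37 of 41 cells. The other 10 and 4 cells had fewer than 10 reads of either kind. The labels give no sex. Xist and Tsix overlap on opposite strands of the X chromosome (103460366 to 103483254 and 103431517 to 103484957), so that their reads cannot be told apart here. Among the 12 higher genes named by the rule 4 were X-linked, namely Tsix, Ddx3x, Ctps2 and C1galt1c1. The 322 other measured X-linked genes had a median difference of -0.19, at percentile 57.4.

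**Figure D3:**
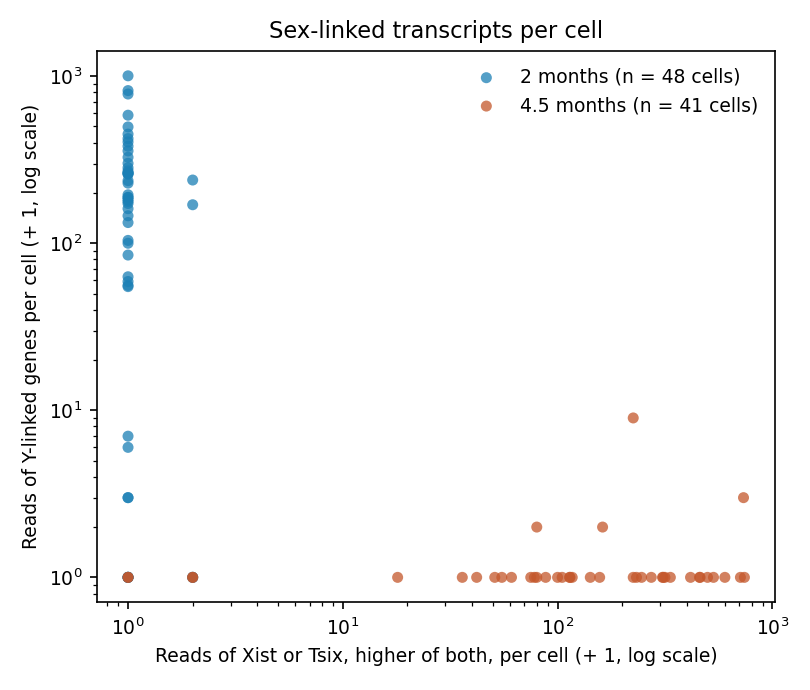
Reads of Xist or Tsix and of Y-linked genes in each of the 89 cells by age, on a log axis. No cell reaches 10 reads of the kind seen at the other age, and 38 cells at 2 months and 37 at 4.5 months have 10 or more reads of their own kind.

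Apart from that of Tsix, the differences of the genes named over all cells were smaller than the larger SD over cells, and the median over all 9989 measured genes was itself lower by age (-0.19, with 64.3% of genes lower). The stem cell identity list no longer stood apart in qNSC cells alone (percentile 3.57), in summed counts (10.6) or in medians over cells (19.5), and the immediate early genes moved to percentile 95.03 without IPC cells and had a median of -0.24 among genes read in 50% of cells. Over qNSC and aNSC cells together, 4 lists were lower at 4.5 months: G1/S (22 of 24 lower, median -0.58), proteasome (32 of 37, -0.66), stem cell identity (15 of 19, -0.62) and lipid synthesis (18 of 22, -0.60). In qNSC cells alone, G1/S lay at percentile 33.6 and the proteasome at 4.87. In aNSC cells alone, some of which carried precursor markers, G1/S lay at percentile 0.

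Within the qNSC class, 32 cells at 2 months and 28 at 4.5 months were compared. Genes of neuronal progenitors and of cholesterol synthesis were lower at 4.5 months. All 5 measured progenitor and neuroblast genes were lower (median -0.89, percentile 0.21); Sox11, a transcription factor of newborn neurons, was read in 1 of 28 against 10 of 32 cells, Prox1, which marks the granule neuron lineage, in 2 against 7, and Stmn1, a microtubule regulator, differed by -0.96. In the lipid and cholesterol synthesis list 14 of 22 genes were lower (median -0.64, percentile 1.96), with Idi1 at 4.26 ± 4.47 against 7.41 ± 3.67, Sqle at 4.01 ± 3.9 against 7.0 ± 3.48 and Cyp51 at 2.65 ± 3.85 against 4.57 ± 4.11. Hes5 was read in 35.7% (18.6 to 55.9) against 78.1% (60.0 to 90.7) of cells, and Wnt7a, a secreted Wnt ligand, in 5 of 28 against 16 of 32.

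Plxnb1, a semaphorin receptor, showed the largest lower difference that met the rule (2.94 ± 3.55 against 6.14 ± 2.78), followed by Hes5 and Pdha1, a subunit of pyruvate dehydrogenase (2.81 ± 3.76 against 5.86 ± 4.02). Map2k2, a kinase of the ERK pathway, and Gpt2, a mitochondrial aminotransferase, differed by -2.85 and -2.68. Prelp was higher at 7.03 ± 3.13 against 3.86 ± 3.91, with a summed CPM of 379 (371 to 387) against 133 (129 to 137). Mertk, a receptor for the uptake of dying cells, was read in 75% (55.1 to 89.3) against 46.9% (29.1 to 65.3) of cells, Tmem176b in 92.9% against 71.9%, and Vcl, an adhesion protein, in 64.3% against 43.8%. Hopx was nearly equal (10.35 ± 1.83 and 10.81 ± 1.23), and Abl1 had a read in 3 of 28 and 4 of 32 cells. Astrocyte markers also differed: S100b had 10 or more reads in 18 of 28 against 14 of 32 cells and Aqp4 in 24 against 23. The astrocyte set led in 22 against 15 cells and the stem cell set in 5 against 17. The median share of astrocyte markers was 66.7% against 62.5% and that of stem cell markers 55% against 65%, so the lead rests on both sets. Leaving out the cells led by markers of another type, an alternative added after the data had been seen, left 17 and 5 cells. The lipid synthesis list then had a median of -0.10 at percentile 62.7 and the progenitor list lay at 26.8. The lipid genes named above stayed lower. Sqle differed by -2.93 rather than -2.99, Cyp51 by -1.82 rather than -1.92 and Idi1 by -2.003 rather than -3.14. Of the 24 genes named by the rule, 17 still met it. Hes5, Stmn1 and Ccnd2 changed direction (to 0.47, 0.54 and 1.98). Hes5 is among the stem cell markers that decided which cells were kept, so its change is in part built in. Vcl and Tmem176b then differed by 0.74 and 0.88 rather than 2.47 and 2.46, and Hopx by -1.21 rather than -0.46. With cells thinned to the same number of reads, 0 lists stood apart. Progenitor genes lay at percentile 5.92, but their median of -0.86 was close to that at full depth. Lipid synthesis lay at 5.46, with a median of -0.38 that was smaller than at full depth. Exons of 10 of the 24 genes named by the rule overlap another gene, among them Plxnb1, Hes5, Pdha1 and Prelp.

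Within the aNSC class, with 11 cells at 2 months and 7 at 4.5 months, cell cycle genes were lower at 4.5 months. In the G1/S list 39 of 41 genes were lower (median -1.80, percentile 0) and in the G2/M list 27 of 32 (median -1.18). Few cells carry the G2/M difference: in thinned cells, 3 of 8 cells at 2 months had reads of 24 to 31 G2/M genes, 2 of these 3 being cells with precursor markers, while the other 5 had 3 to 7 and the 7 cells at 4.5 months 5 to 8. Rfc2, a subunit of the clamp loader of DNA replication, was read in 2 of 7 against 11 of 11 cells (1.82 ± 3.13 against 6.47 ± 2.56), and Mcm2 in 1 of 7 against 6 of 11. Nuclear genes of oxidative phosphorylation (66 of 83 lower, median -0.51), lipid synthesis (14 of 21, -1.26) and oxidative stress defence (19 of 27, -0.98) also stood apart. Progenitor genes were higher (7 of 11, median 0.83), with Sox4 at 5.54 ± 3.36 against 1.34 ± 2.05, and ribosomal proteins had a median of 0.12, which was -0.30 in thinned cells. Precursor markers were present in 4 of the 11 and 3 of the 7 cells. Without the cells with markers of other types, which left 6 and 4, the progenitor list had a median of -0.20 at percentile 44.1. G2/M then lay at 4.94 with a median of -0.95 rather than -1.18. Oxidative phosphorylation lay at 2.58 with -0.47 rather than -0.51, and oxidative stress defence at 22.7. Thinned, 3 of the 7 lists stood apart, and lipid synthesis lay at percentile 8.56 and oxidative stress defence at 13.2. The 6 cells of 2 months without other-type markers included cells of 252274, 262315, 343162 and 472000 counts. These belong to the run of low totals described above, and thinning left out 3 of them. No 4.5-month aNSC cell had fewer than 714874 counts. What part this run has in the aNSC age differences was not tested.

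Within the IPC class, with 5 and 6 cells, G2/M genes were higher at 4.5 months (37 of 51, median 0.78, percentile 100). In thinned cells this median fell to 0.19. Single thinned cells had reads of 7 to 50 G2/M genes at 4.5 months and of 5 to 52 at 2 months, so the ages overlap. The 4.5-month cells had reads of fewer genes, with medians of 3911 against 5184 and of 3772 against 4673 when thinned, and a median of 32.5% against 50% of stem cell markers at 10 reads. Chek1, a checkpoint kinase of dividing cells, was read in 5 of 6 against 1 of 5 cells. Dcx, a microtubule protein of migrating neuroblasts, was read in 0 of 6 against 3 of 5 cells, at least 373-fold lower in summed CPM. The lipid synthesis list was lower (15 of 18, median -1.74), with Sqle at 3.99 ± 4.08 against 8.14 ± 0.98, as were stem cell identity (13 of 15, -1.42), lysosome (21 of 29, -1.46), glycolysis (11 of 16, -1.18), Wnt (16 of 16, -1.57), inflammatory (6 of 6, -2.92) and ABL and SRC kinase signalling genes (14 of 20, -1.91). In the last list Fyn, a SRC family kinase, stood at 1.58 ± 2.83 against 6.72 ± 3.92, whereas Abl1 was read in 3 of 6 and 2 of 5 cells. Thinned, which left 4 and 6 cells, 2 of these 8 lists and 3 others stood apart, with G2/M at percentile 93.4, inflammatory signalling at 24.7 and Wnt signalling at 23.5.

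The activation score sets cell cycle and progenitor genes against stem cell identity genes. It differed little between the ages over all cells and was somewhat higher at 4.5 months in qNSC cells. Its median was -0.43 at 2 months and -0.35 at 4.5 months over all cells, -0.46 and -0.38 over qNSC and aNSC cells, and -0.55 and -0.41 in qNSC cells. In qNSC cells the means were -0.60 ± 0.28 and -0.40 ± 0.27 (SD over cells), and the 4.5-month median lay near the 2-month upper quartile of -0.405. None of the lists that raise the score lay above the middle of the random lists there. G1/S was at percentile 33.6, G2/M at 39 and progenitor genes at 0.21. The subtracted stem cell identity list had a median of -0.58, so the higher score does not show higher cell cycle or progenitor genes. These score differences were smaller than the SD over cells, which describes single cells and not a spread between animals. In the 11 and 7 aNSC cells the medians were 0.03 and 0.73 but the means 0.53 ± 1.11 and 0.31 ± 0.80, so the direction depends on the summary. Over both ages, the 7 aNSC cells with precursor markers scored 0.86 to 2.42 and the other 11 scored -0.95 to 1.35. Both summaries therefore lean on the cells with precursor markers. In the 5 and 6 IPC cells the medians were 1.28 and 2.37 and the means 1.71 ± 0.82 and 2.29 ± 1.002, which differ by less than either SD. In thinned cells, reads of at least 5 G2/M genes were present in 76.2% (60.5 to 87.9) of 42 cells at 2 months and 78.9% (62.7 to 90.4) of 38 cells at 4.5 months. This share was 73.3% and 68% in qNSC cells, of which 0 had 10 or more reads of Mki67, so it does not set cycling cells apart.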

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

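The tests of the sex-linked reads, those of mixing and free RNA for the precursor markers, and those of the class mix and of astrocytes for the lipid genes were chosen after the results they bear on had been seen.

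Sex-linked reads were found in genes that no planned comparison had used. Of the 2-month cells 38 had 10 or more reads of a Y-linked gene, of the 4.5-month cells 37 had 10 or more reads of Xist or Tsix, and 0 cells had 10 or more reads of the other kind, which argues against a mixture of sexes within an age. A higher output of the whole X chromosome at 4.5 months was not seen, since the other X-linked genes lay at percentile 57.4 among matched random lists. The reads are consistent with male cells at 2 months and female cells at 4.5 months. Sex and age then coincide in each cell that could be read, all but 10 and 4, 0 kinds of these transcripts being shared by the ages. The sex of the animals and their age therefore cannot be told apart as the source of any other difference between the ages given here. Age as named by the design stays an open and untested explanation.

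Oligodendrocyte precursor markers stood out in 7 of the 18 aNSC cells. A stem cell and a precursor sorted together would bring stem cell markers at the level of the other aNSC cells, but the 7 cells had a median of 30% of them at 10 reads, where the other 11 had 40% to 75%, and Hopx, Gfap and Sox9 were at that level in 0 of 7, although the 7 had more genes with a read (median 4999 against 4145) and more counts (944913 against 798669), as a pair of cells would. Free RNA or carry-over would spread to other cells, and 0% of the other 82 had 10 reads of Pdgfra or Sox10. Neu4, Lhfpl3 and Gpr17 had 10 or more reads in 0 of the 82 and Cspg4 in 1. Olig1, Olig2 and C1ql1, however, had them in 26, 11 and 9. The absence of the first markers argues against free RNA for those genes. It leaves the question open for Olig1, Olig2 and C1ql1, whose reads in other cells were not examined further. That precursor cells passed the sort through an active Nestin promoter stays open: Nes was read in 0 of the 7, but also in only 5 of 60 qNSC cells (8.33%), so the limit set beforehand, at most 1 of 7, could not tell the cases apart and was revised once this was seen. A candidate explanation is that these 7 are precursor cells rather than activated stem cells, a hypothesis from the same data; no biological alternative was tested.

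Lipid and cholesterol synthesis genes were lower at 4.5 months over all cells. Cell types other than astrocytes do not account for this over all cells, as the list lay at percentile 0.30 without the 12 cells that carry their markers. In qNSC cells it then lay at 2.88, with a median of -0.68 rather than -0.64, so the difference itself was not smaller. A different mix of classes is argued against by medians of -0.64, -1.26 and -1.74 within qNSC, aNSC and IPC cells. The percentile in qNSC cells, 1.96, is however near the limit of 2.5. Fewer reads per cell at 4.5 months stays open: with thinned cells the list lay at percentile 1.93, but 20 repeats of the thinning, added afterwards, gave 0.90 to 3.70 over all cells, with 16 at or below 2.5, and 4.15 to 11.5 in qNSC cells. Astrocytes among the qNSC cells stay open as well, since without the cells led by markers of another type the list lay at percentile 62.7 in qNSC cells (17 and 5 left) but at 0.98 over all cells, where the mix of classes then differs between the ages. Sex, by the split described above, stays open too, and a lower expression of these genes with age may be 1 explanation, untested with 1 sample per age.

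The highest total count among the 7 aNSC cells of 4.5 months was 1597526, against 714874 to 1095663 in the other 6, and that cell was among those with precursor markers. It was 1 of 9 sets of 5 to 7 cells to go beyond the limit of Dixon's outlier test, which about 1 in 20 sets does by chance. Its gap to the next cell was 0.5686 of the range, barely beyond the limit for 7 cells. The 9 sets were total counts, genes with a read and activation score in the same groups of cells, so they are not independent.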

How the results depend on the processing

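Between 17 and 24 of the 24 genes named by the rule still met it in each comparison and alternative. The lipid and cholesterol synthesis list stood apart in 18 of 18 alternatives over all cells (percentiles 0 to 2.13), stem cell identity in 15 of 18 and immediate early genes in 13 of 18. Thinning counts here as a single draw. Its 20 repeats put the lipid list at percentiles 0.90 to 3.70, with 16 at or below 2.5. Centring moved the median difference of all genes between the ages from -0.19 to 0.10.

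For the gene list medians by age, 3 lists stood apart over all cells, against 6 in summed counts, 6 in thinned cells, 8 without the 10% of cells with the fewest genes, 5 with detection at 10 reads, 13 without the cells whose leading markers were of another type (26 and 15 cells left) and 6 without the 12 cells with other-type markers. In qNSC cells 2 stood apart, against 8 with a pseudocount of 10, 0 in thinned cells and 1 without other-type cells. Thinned, aNSC cells had 3 rather than 7 and IPC cells 5 rather than 8. Without other-type cells, 2 lists crossed to the other side of the random lists, progenitor identity in aNSC cells by age (percentile 44.1) and quiescence regulators in aNSC against qNSC (percentile 70.6), and the medians of interferon genes and fatty acid oxidation in aNSC against qNSC changed sign (to 0.08 and 0.37). Without the qNSC cells led by markers of another type (17 and 5 left), the lipid list by age in qNSC cells lay at percentile 62.7. Hes5 differed by 0.47 rather than -3.11, but it is itself among the stem cell markers that decided which cells were kept. In each case the cause was not tested.

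New clusterings did not recover the classes (adjusted Rand index 0.33 for k-means, 0.30 for Ward clustering without cell cycle genes), so shares of the clusters matched to a class are not shares of its cells; the k-means cluster matched to aNSC held 30 qNSC and 4 aNSC cells. With k-means, the class share by matched cluster was 39.6% at 2 months and 34.1% at 4.5 months for qNSC, 37.5% and 39.02% for aNSC, and 22.9% and 26.8% for IPC. With Ward clustering it was 39.6% and 36.6% for qNSC and 39.6% and 39.02% for aNSC. The cause was not tested beyond these counts.

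No paired analysis was possible because no label pairs the cells or names an animal. The numbers in the titles were read as cell names only, and no test was run. Depth without mitochondrially encoded genes was not run, since none are listed.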

Other observations

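The deposited colours divide the 60 qNSC cells further, into 25, 9 and 26 cells. Some stem cell and astrocyte genes differ between these subsets. Frzb, a secreted Wnt antagonist, was read in 15 of 25 cells of the first subset, 0 of 9 of the second and 1 of 26 of the third. Gfap had means of 8.52, 4.45 and 7.5 in log2(CPM + 1), and Stmn1 was read in 88.0%, 33.3% and 69.2% of cells. Astrocyte markers had median shares of 58.3%, 66.7% and 75% in the subsets, and stem cell markers 65%, 50% and 55%. Among the astrocyte markers, S100b was read in 6 of 25, 7 of 9 and 21 of 26 cells. Gjb6 was read in 18, 9 and 25 of these cells, whereas Fam107a, in 23, 7 and 24, was not less often read in the first subset than in the second. The 2-month cells numbered 15, 4 and 13 and the 4.5-month cells 10, 5 and 13, so that each subset held cells of both ages. The genes given here were chosen after their values were seen, and since the subsets come from the deposited annotation, differences between them are in part built in.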
